A study of Mus musculus with 6 samples.

How the data were processed

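RNA from mouse bone marrow-derived macrophages was sequenced in 6 libraries, 3 labelled as global CD22 knockout and 3 as wild type. Per the labels, the mice were C57Bl/6, marrow cells were grown with medium conditioned by L929 fibroblasts, which supplies macrophage growth factor, and the macrophages were then kept for 48 hours with 20 ng/mL IL-4 in 25% L929-conditioned medium. Poly(A) RNA was made into strand-specific libraries and sequenced as read pairs, per the labels' protocols. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Each library carries a batch code of its own, so batch could not enter a fit.

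The values are FPKM per gene (fragments mapped to a gene, scaled to its transcript length and to all mapped fragments) in a table the authors deposited, with no read counts. The same table holds the authors' fold, which per the values is the ratio of mean knockout to mean wild type FPKM, and its log2, both deposited by the authors. It also holds a p-value and a q-value per gene from the authors' own comparison, per the file headers. How that comparison was made is not given in the sources used here. The submitters' processing notes name cutadapt, FastQC, HISAT2, StringTie, DESeq2 and edgeR, with no versions and no roles. The genome build and annotation are not given in the sources used here. Positions were therefore looked up by gene ID in GENCODE release 21 for mouse (GRCm38), which held 31792 of the 31883 gene IDs (99.7%).

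FPKM values do not give the depth of a library, which is unknown here, so no counting intervals were computed. The most common ratio of low FPKM values of the same gene between libraries gave depths relative to wild type library 1 of 1.11, 1.10 and 1.10 for the knockout-labelled libraries and 1.02 and 0.971 for wild type libraries 2 and 3. FPKM is a share of a library, so a few abundant transcripts can shift the values of all other genes. An FPKM of 0 can be a failed estimate, so such genes are described as listed at 0.

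The plan made before the data were examined held a test for read counts and another for normalized values, and the second applied. FPKM values were put on the scale log2(FPKM + 1), and the 10777 genes with an FPKM of at least 1 in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, robust moderation and no covariates. The test was 2-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p below 0.05 are described as called. Log2 fold changes are differences on the log2(FPKM + 1) scale, which understate the change of low genes, and the folds given beside them are ratios of mean FPKM.

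Also fixed before the data were examined were 29 gene lists, the thresholds, the processing alternatives and the rule for the genes named. That rule takes Cd22, then the 10 largest rises and the 10 largest falls among called genes with a mean FPKM of at least 1 and no overlap between the groups, leaving out predicted genes, then the 4 members of each list with the smallest p, and every sex-linked gene. Genes outside the rule are marked as chosen after their values were seen, and not every gene that the rule names is reported here. Lists were tested with limma's camera, 2-sided, with a preset correlation of 0.01 between genes, adjusted over the 29 lists, and again with camera using an estimated correlation and with fry. GO and KEGG terms that the deposited table gives were tested in the called genes of a direction with at least 20 called genes, by a 1-sided Fisher's exact test on terms of 10 to 500 genes. Called genes beside Cd22 were counted among its fixed neighbours and within 10 Mb, with a 2-sided Fisher's exact test.

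On simulated data for this comparison over 10777 genes, limma recovered 83.2% of genes changed by 0.50 on the log2 scale, 97.1% of those changed by 1.00 and 99.4% of those changed by 2.00, and called 73 of 52885 unchanged genes. Each run changed 200 genes and drew independent normal noise with the moderated SD of each gene. Having more changed genes loosens the adjustment, so these shares can be too high for the real libraries. Camera recovered 20 of 20 simulated lists moved by 0.30 and called 1 of 580 unmoved lists, in simulated genes with no correlation between them. The count of close gene pairs was also tested on simulated sets over the 10777 genes, where 4.5% of random gene sets had a p of at most 0.05, and 84.0% of sets with 6 planted neighbours did.

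The alternatives were a pseudocount of 0.1, no filter on low values, an FPKM of at least 5, median centring, quantile normalization, no robust moderation, a replicate block, other thresholds, each library left out in turn and, for distances to Cd22, 5 and 20 Mb. Lists of epididymis, skeletal muscle and adipocyte transcripts, and fits of protein-coding genes alone or without wild type libraries 1 and 2, were added after seeing the data. Values were tabulated with the R package data.table, version 1.17.8, and drawn with matplotlib 3.10.9 in Python 3.11.15.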

Results

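The transcriptomes of 6 cultures of IL-4-treated bone marrow-derived macrophages were compared, 3 labelled as CD22 knockout and 3 as wild type. CD22 is a sialic acid-binding receptor of the Siglec family, best known as an inhibitory receptor of B cells, and IL-4 drives macrophages towards the alternatively activated, M2-like state. The deposited table held 31883 genes, of which 25499 had a value above 0 in at least 1 library. Read depth is unknown because only FPKM values were given, and the FPKM of a library summed to between 314441 and 348332. Mitochondrially encoded transcripts took 17.2%, 20.4% and 15.6% of the FPKM in the knockout-labelled libraries and 11.8%, 11.7% and 16.5% in the wild type libraries, and mt-Co1 was the most abundant transcript in each. Correlations between libraries across genes were 0.988 to 0.993 within groups and 0.986 to 0.991 between groups. The first principal component, with 33.1% of the variance, placed the knockout-labelled libraries at 8.55, 10.9 and 7.52 and the wild type libraries at -13.1, -9.64 and -4.21.

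Cd22 itself (ENSMUSG00000030577) was not lower in the libraries labelled CD22 knockout beyond the spread between libraries. Its FPKM was 8.85, 8.21 and 9.53 in those libraries, a mean of 8.86 ± 0.661 (SD, n = 3), and 8.95, 9.36 and 10.6 in the wild type libraries, a mean of 9.65 ± 0.883 (SD, n = 3). The log2 fold change was -0.11 with a standard error of 0.087 (limma, adjusted p = 0.695). The gene lies on the minus strand of chromosome 7 from 30865402 to 30880342 in GRCm38. Gene-level FPKM can include transcript outside a deleted part, and the deposited values do not separate exons, so the Cd22 level neither bears out nor contradicts a deletion of part of the gene. All directions below are for the libraries labelled CD22 knockout relative to wild type.

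Which genes differed between the genotypes under IL-4 was the main comparison. Axl, C1qa and Rab4a were among the 16 genes that rose in the libraries labelled CD22 knockout. Axl, a receptor tyrosine kinase for phagocytosis of apoptotic cells, rose from 6.97 ± 1.37 to 15.8 ± 1.30 FPKM (SD, n = 3 each), which is 2.26-fold (log2 fold change 1.08, SE 0.118, limma, adjusted p = 0.0037). The scavenger receptor gene Scarf1 rose 1.54-fold (log2 fold change 0.57), and the matrix metalloproteinase gene Mmp14 rose 1.78-fold (log2 fold change 0.72). C1qa, a chain of the complement recognition molecule C1q, rose 1.48-fold from 406 ± 30.4 to 602 ± 37.2 FPKM. Rab4a, a small GTPase of endosome recycling, rose 2.82-fold from 2.11 ± 0.0352 to 5.95 ± 0.204 FPKM (limma, adjusted p = 3.8e-05). The largest rises on the log2 scale were those of Cnbd2 (1.73, 5.96-fold) and of Olfml3, which encodes a secreted olfactomedin-like protein (1.40, 11.0-fold, from 0.199 ± 0.0513 to 2.19 ± 0.596 FPKM). Capza1, an actin capping protein subunit, rose 2.00-fold, and Dubr and the mitochondrial transfer RNA mt-Tr rose by 0.62 and 0.58 on the log2 scale. The call of mt-Tr lay close to the threshold (limma, adjusted p = 0.0498) and was lost when any of 5 libraries was left out. Its q in the authors' deposited table was 0.934.

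Among the genes that fell, Kif3c, a kinesin motor subunit, fell from 10.1 ± 0.301 to 2.62 ± 0.146 FPKM, so that it was 3.85-fold higher in wild type (log2 fold change -1.62, limma, adjusted p = 2.5e-06). The neuropeptide gene Npy fell from 17.2 ± 3.70 to 8.96 ± 0.287 FPKM (log2 fold change -0.85), and the deubiquitinase gene Uchl1 fell from 6.62 ± 1.22 to 3.34 ± 0.284 FPKM (log2 fold change -0.80). Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase (ENSMUSG00000025453), fell from 5.52 ± 0.886 to 1.84 ± 0.481 FPKM (log2 fold change -1.20). Falls in Tbc1d23 (-0.85), Tmem154 (-0.85), Tmod1 (-0.77) and C77080 (-0.74) were of similar size on the log2 scale. Hist1h2al, a histone H2A gene, was listed at 0 in each library labelled CD22 knockout and at a mean of 8.70 ± 3.00 FPKM in wild type. The pseudogene Capza1-ps1 fell by 1.66 on the log2 scale, opposite to Capza1. Values of Capza1, Capza1-ps1 and Hist1h2al are uncertain because near-identical copies can share reads, as are those of Nnt, whose name 2 overlapping gene IDs carry. Cd47, the "don't eat me" signal recognised by phagocytes, and the hypoxia-inducible factor gene Epas1 were chosen after their values were seen, and both fell, by 0.61 and 0.72 on the log2 scale.

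**Figure D1:**
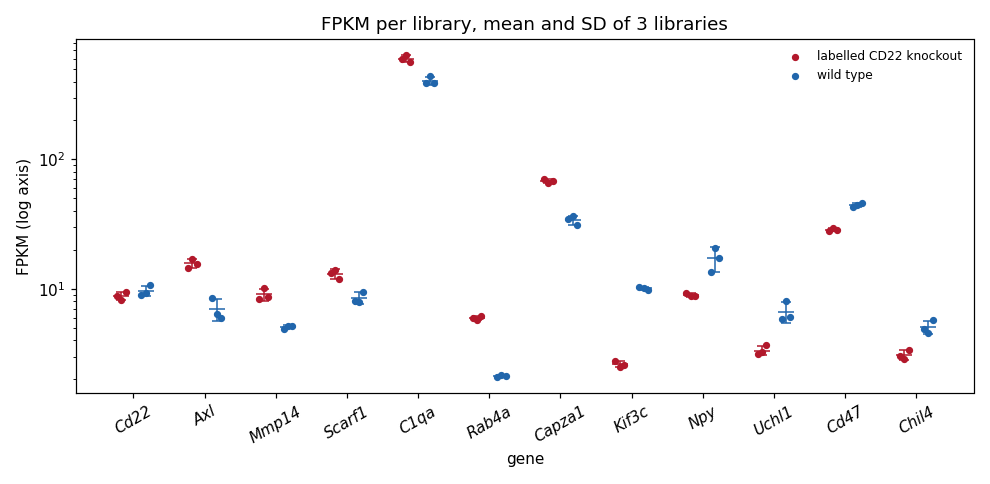
FPKM of 12 genes on a log axis in each of the 6 libraries, red for the libraries labelled CD22 knockout and blue for wild type, with the mean and SD of 3 libraries. Cd22 overlaps between the groups, with means of 8.86 and 9.65 FPKM, while the values of the 11 called genes do not overlap; Cd47 was chosen after its values were seen.

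In all, limma called 44 of the 10777 genes tested, 16 higher and 28 lower in the libraries labelled CD22 knockout, and 10 of them changed by at least 1.00 on the log2 scale. The groups did not overlap in any of the 44 called genes, nor in 1847 of the genes tested (17.1%, where chance gives 10%), and 1182 genes (11.0%) had an unadjusted p under 0.05. In the authors' deposited table, 221 genes had a q below 0.05 and 74 were marked significant, 17 higher and 57 lower. Just as many, 74, had both that q and an authors' log2 fold of at least 1.00 in size. The 44 calls here carry no fold threshold, so the 2 counts are not on the same terms. Of the 44 genes called here, 39 had a q below 0.05 in the authors' deposited table and 15 were among the 74 marked there. Of those 74, 21 were among the genes tested here, and 16 had a value above 0 in 1 library alone, 13 of them in wild type library 2. The count of 44 fell to 28 without CD22_KO replicate 2 and rose to 92 without CD22_KO replicate 3. It was 3 with no filter on low values and was 11 without wild type libraries 1 and 2, which held transcripts of other tissues (a fit added after the data were seen). Of the 21 called genes that the rule names, 12 were called with any single library left out. For the other 9 the highest adjusted p came without WT replicate 1 for C1qa (0.204), mt-Tr (0.194), Scarf1 (0.148), Tmem154 (0.0904) and C77080 (0.0835). It came without WT replicate 3 for Npy (0.155), Chil4 (0.103) and Dubr (0.0669), and without CD22_KO replicate 2 for Hist1h2al (0.0962).

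The series title raises inflammatory expression and endocytosis as its themes, which the fixed lists cover. Pro-inflammatory genes leaned higher in the libraries labelled CD22 knockout, but 0 of the 28 measured were called over all genes by limma, and 8 had an unadjusted p under 0.05. With p adjusted over the list alone, 4 were higher. These were Fpr1, a formyl peptide receptor (17.4 ± 2.99 against 11.4 ± 1.12 FPKM, SD, n = 3 each), and Tnf (18.4 ± 2.05 against 13.9 ± 1.10 FPKM). They were joined by the scavenger receptor Marco (10.1 ± 2.26 against 6.52 ± 0.433) and Nfkbia, an inhibitor of NF-kB (29.5 ± 1.69 against 24.5 ± 0.891). The list's median log2 fold change was 0.14, with 21 members higher and 7 lower (camera, adjusted p = 8.1e-04), and it was not called with an estimated correlation (adjusted p = 0.892). Its call was lost without CD22_KO replicate 2 (adjusted p = 0.0722). Major histocompatibility complex class II and co-stimulation genes were higher in 11 of 12 members, such as H2-DMb1 (34.7 ± 5.18 against 29.0 ± 3.69 FPKM) and Cd83 (17.0 ± 1.92 against 14.7 ± 1.05). Limma called 0 over all genes and 0 adjusted over the list alone, 1 had an unadjusted p under 0.05, and the median was 0.22 (camera, adjusted p = 0.0108; adjusted p = 0.626 with an estimated correlation). That call was lost without CD22_KO replicate 1 and without WT replicate 2 (adjusted p up to 0.117). Interferon-stimulated genes had 0 of 37 called over all genes, 0 adjusted over the list alone and 3 with an unadjusted p under 0.05, with a median of -0.06 and Gbp2 at 11.7 ± 1.46 against 15.7 ± 3.53 FPKM (camera, adjusted p = 0.469).

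Endocytic and phagocytic receptor genes moved both ways. Of 38 measured, Axl, Scarf1 and C1qa rose and 0 fell over all genes, and adjusted over the list alone Marco was also higher and Tlr4, the lipopolysaccharide receptor, was lower (21.3 ± 1.90 against 27.6 ± 2.23 FPKM). This list's median log2 fold change was -0.03 while its mean was 0.05 and camera placed it higher, so they differ in sign (camera, adjusted p = 0.176). Endocytosis machinery had Rab4a as the 1 called gene of 54, over all genes and adjusted over the list alone, with a median of -0.05 (camera, adjusted p = 0.569). Values of its other members included Bin1 at 25.0 ± 2.62 against 19.6 ± 1.07 FPKM and Rab5b at 28.4 ± 1.77 against 34.4 ± 2.24 FPKM. By fry's test for change in either direction the adjusted p was 0.00227 for the receptors and 1.2e-05 for the machinery, and by fry's directional test 0.251 and 0.901. A test for either direction can be carried by few genes, and Rab4a is the 1 called gene of the machinery. Whether the machinery result holds without Rab4a was not tested. Lysosome genes had 0 of 46 called over all genes, 0 adjusted over the list alone and 3 with an unadjusted p under 0.05, with Atp6v1a, a proton pump subunit, at 125 ± 5.01 against 159 ± 11.2 FPKM (camera, adjusted p = 0.684). The calls of Scarf1 and C1qa were each lost without CD22_KO replicate 1, CD22_KO replicate 2 or WT replicate 1. Scarf1 was also lost without WT replicate 2 (adjusted p up to 0.148) and C1qa without WT replicate 3 (adjusted p up to 0.204).

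Complement genes had 10 of 13 members higher, and C1qa rose, over all genes and adjusted over the list alone. C1qc (513 ± 33.8 against 415 ± 31.9 FPKM) and C1qb (853 ± 42.6 against 690 ± 70.6) lay on the same side without being called. Cfd, an adipocyte product, was at 0.594 ± 0.322 against 6.44 ± 8.29 FPKM, and wild type library 1 held the highest sum of adipocyte transcripts. Median and mean of the complement list were 0.10 and -0.01 and differ in sign (camera, adjusted p = 0.0339, higher; adjusted p = 0.626 with an estimated correlation). The call was lost without CD22_KO replicate 2, CD22_KO replicate 3, WT replicate 1 or WT replicate 2 (adjusted p up to 0.107). Siglec and sialic acid genes had 0 of 24 called over all genes and 4 with an unadjusted p under 0.05 (camera, adjusted p = 0.810). That list joins members of the family of CD22 with genes of sialic acid metabolism and of signalling, so its counts are not for the family alone. Adjusted over the list alone, Siglece was higher (10.8 ± 1.76 against 5.85 ± 1.64 FPKM) and Cd33 lower (13.2 ± 0.385 against 16.3 ± 0.830 FPKM). Both genes lie on chromosome 7 within 20 Mb of Cd22, and whether DNA linked to Cd22 plays a part in their values was not tested.

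Genes of the IL-4 response were not called as a group. Of 33 measured, Chil4, a chitinase-like protein, fell from 5.07 ± 0.589 to 3.08 ± 0.262 FPKM over all genes and adjusted over the list alone. Its call was lost without CD22_KO replicate 1, CD22_KO replicate 2, WT replicate 1 or WT replicate 3 (adjusted p up to 0.103). The median was 0.00 (camera, adjusted p = 0.684). Clec10a, the gene of a lectin receptor, was at 59.8 ± 6.10 against 48.6 ± 8.53 FPKM, and Chil3, a chitinase-like protein of the same family, at 1256 ± 199 against 1578 ± 139 FPKM. Chil4 lies close to Chil3 on chromosome 3 at a far lower FPKM, and whether it takes reads from Chil3 was not tested. Disease-associated microglia genes had 6 of 24 members higher and 18 lower, with Axl called higher over all genes (camera, adjusted p = 0.469). Csf1, the macrophage growth factor, was lower and Axl higher when adjusted over the list alone, with Csf1 at 4.72 ± 0.289 against 6.94 ± 0.676 FPKM (limma, adjusted p = 0.0506 over all genes).

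Glycolysis and hypoxia genes were higher in 18 of 27 members, with 0 called over all genes, 6 with an unadjusted p under 0.05 and Gapdh higher adjusted over the list alone (7.32 ± 0.619 against 5.55 ± 0.292 FPKM). The FPKM of Gapdh lay below that of Slc2a1, and whether near-identical copies take reads from Gapdh was not tested. Slc2a1, a glucose transporter, was at 33.4 ± 2.25 against 27.2 ± 1.61 FPKM, and the list's median was 0.06 (camera, adjusted p = 0.0108; adjusted p = 0.892 with an estimated correlation). NRF2 target genes were higher in 15 of 18, such as Hmox1, which degrades heme (194 ± 13.5 against 158 ± 11.3 FPKM), with 0 called over all genes, 0 adjusted over the list alone and 5 with an unadjusted p under 0.05 (camera, adjusted p = 0.0208; adjusted p = 0.892 with an estimated correlation). The glycolysis call was lost without CD22_KO replicate 2 or WT replicate 2 (adjusted p up to 0.0656), and the NRF2 call without CD22_KO replicate 2, WT replicate 1 or WT replicate 3 (adjusted p up to 0.259). Oxidative phosphorylation genes were lower in 50 of 66 with a median of -0.07 (camera, adjusted p = 0.229), cholesterol synthesis genes in 15 of 22 (adjusted p = 0.569) and unfolded protein response genes in 15 of 22 (adjusted p = 0.469). Lipid handling genes were lower in 16 of 26 (adjusted p = 0.469), and cell cycle genes were higher in 29 of 43 (adjusted p = 0.0836). Each of these lists had 0 called genes over all genes and 0 adjusted over the list alone, with an unadjusted p under 0.05 in 2 oxidative phosphorylation, 1 cholesterol synthesis, 3 unfolded protein response, 5 lipid handling and 1 cell cycle genes. Their examples were Uqcrb (18.8 ± 1.36 against 23.0 ± 2.32 FPKM), Insig1 (9.16 ± 1.20 against 11.7 ± 1.57), Herpud1 (33.8 ± 1.18 against 39.4 ± 1.23), Plin2 (218 ± 8.10 against 273 ± 24.4) and Tk1 (4.46 ± 0.532 against 3.47 ± 0.437). The share of mitochondrially encoded transcripts, at 15.6% to 20.4% in the libraries labelled CD22 knockout, was also higher on average there than in wild type.

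**Figure D2:**
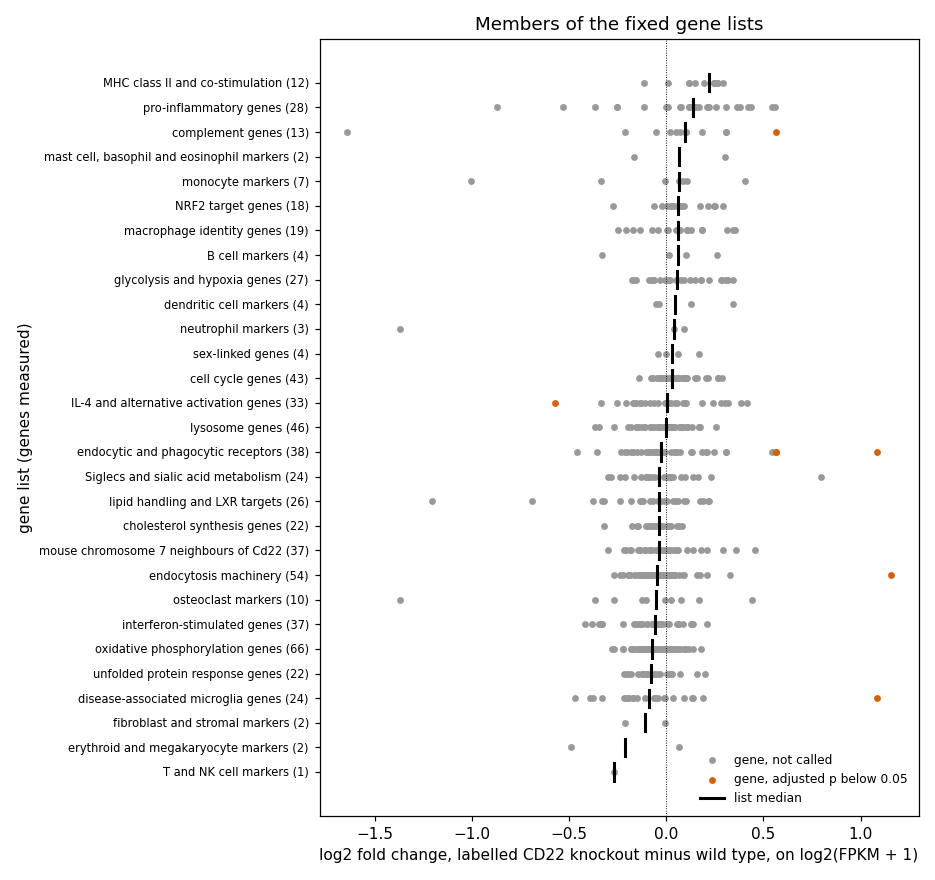
Log2 fold changes, libraries labelled CD22 knockout minus wild type on log2(FPKM + 1), of the measured members of the 29 fixed gene lists, with list medians as black bars and called genes in orange. Most members lie close to 0, and list medians run from -0.27 for a single T and NK cell marker to 0.22 for the major histocompatibility complex class II list.

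Of the 29 lists, camera called 5 with the preset correlation, all higher (pro-inflammatory, glycolysis and hypoxia, class II, NRF2 and complement genes), and 0 with an estimated correlation. The directional fry test called 0, and fry called 6 for change in either direction (endocytosis machinery, receptors, complement, glycolysis and hypoxia, Siglec and sialic acid, and microglia genes). Some of these lists share members, such as Axl in the receptor and microglia lists and C1qa in the receptor and complement lists. Without CD22_KO replicate 2 the preset test called 1 list, without WT replicate 2 it called 2, and other splits of the same 6 libraries called up to 8 lists. Signs of median, mean and camera also differed for the lysosome, monocyte, neutrophil and chromosome 7 lists.

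Markers of macrophages and other cell types gave 0 called genes over all genes by limma. Macrophage identity genes were higher in 13 of 19, with 0 adjusted over the list alone, 3 with an unadjusted p under 0.05 and Csf2ra at 231 ± 19.6 against 182 ± 13.7 FPKM (camera, adjusted p = 0.113). Monocyte markers had 4 of 7 higher (adjusted p = 0.841) and osteoclast markers 4 of 10 (adjusted p = 0.619), with 0 adjusted over the list alone in both and 1 and 2 genes with an unadjusted p under 0.05. B cell markers had 3 of 4 higher, 0 adjusted over the list alone and 1 with an unadjusted p under 0.05 (adjusted p = 0.619), with Ighm at 5.08 ± 0.317 against 4.15 ± 1.10 FPKM. Among 3 neutrophil markers, Mmp9 was lower adjusted over the list alone (29.4 ± 11.0 against 75.4 ± 15.9 FPKM; camera, adjusted p = 0.569). Among 4 dendritic cell markers Batf3 was higher adjusted over the list alone (5.18 ± 0.600 against 3.88 ± 0.664 FPKM; camera, adjusted p = 0.469). The T and NK cell, mast cell, stromal and erythroid lists had 1, 2, 2 and 2 measured genes, 0 called over all genes, 0 adjusted over the list alone and 0 with an unadjusted p under 0.05. Their adjusted p by camera was 0.469, 0.684, 0.849 and 0.716. Sex-linked genes had 0 of 4 called over all genes, 0 adjusted over the list alone and 0 with an unadjusted p under 0.05 (camera, adjusted p = 0.478). Xist was listed at 0 in 5 of the 6 libraries and at 0.002579 FPKM in WT replicate 3, and the Y-linked gene Ddx3y was at 15.0 ± 0.638 against 14.3 ± 1.23 FPKM.

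Genes next to Cd22 were examined because DNA beside a targeted gene can come from another mouse strain. Of 37 fixed neighbours measured on chromosome 7, 0 were called over all genes, against 44 of 10739 elsewhere (2-sided Fisher's exact test, p = 1, odds ratio up to 26.5), and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 1 neighbour was higher, and without WT replicate 2 the count called over all genes was 1. As a list, the neighbours had a median of -0.04 (camera, adjusted p = 0.619). Within 10 Mb of Cd22, 2 of 153 genes were called, Axl and the predicted gene Gm2058 (chosen after its values were seen), with an odds ratio of 3.34 (0.388 to 13, Fisher's exact test, p = 0.129). Axl starts at position 25757273 of chromosome 7 in GRCm38 and ends at 25788705, just outside the 5 Mb window set as an alternative. Whether DNA linked to Cd22 plays a part in the rise of Axl was not tested.

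No annotation term was called for the genes that fell. Of 1805 GO and KEGG terms tested on the 28 lower genes, 0 passed an adjusted p of 0.05 by Fisher's exact test, and 47 had an unadjusted p under 0.05. The smallest unadjusted p was 0.0017, for the term on lipolysis in adipocytes with Adcy2 and Npy, followed by 0.0018 for the axon term with Kif3c, Map6 and Uchl1. The 16 higher genes were fewer than the 20 set as a minimum and were not tested.

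**Figure D3:**
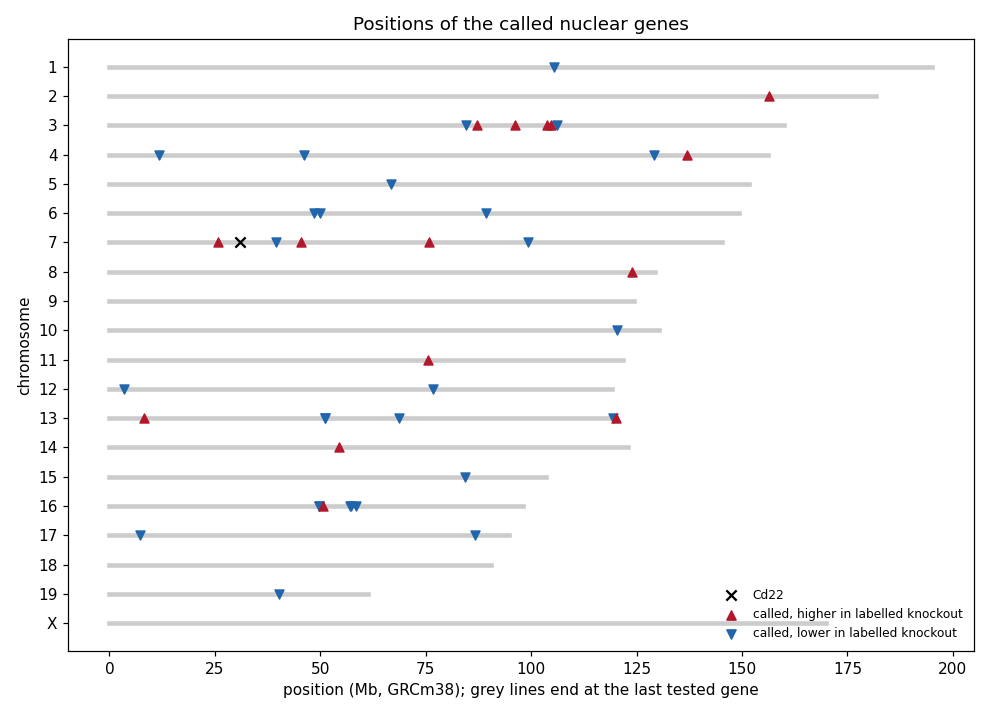
Positions of the called nuclear genes along the mouse chromosomes in Mb (GRCm38), with triangles pointing up for genes higher and down for genes lower in the libraries labelled CD22 knockout, and a cross at Cd22. Chromosomes 3, 13 and 16 hold 6 called genes each and chromosome 7 holds 5.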

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

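The tests of shared reads and of epididymis genes, and the choice of genes below the filter, were made after the values were seen; the splits of the libraries and the second muscle list were set before their results were seen. Genes too low for the main test can still part the groups. In that range, 6 genes outside the predicted ones had groups without overlap, means at least 4 times apart, a higher mean of at least 0.3 FPKM and a q below 0.05 in the authors' deposited table. Groups without overlap arise by chance in 10% of genes. These 6 were picked for the difference itself, so that rate does not apply to them and their separation is not a test. Ffar1, a fatty acid receptor gene 3.84 kb from Cd22, was at 0.517 ± 0.079 FPKM in the libraries labelled CD22 knockout and 0.0434 ± 0.030 in wild type (SD, n = 3 each), 11.9-fold. Lrmda was at 0.989 ± 0.098 against 0.108 ± 0.038 FPKM, and Gpr31c at 0.551 ± 0.104 against 0.136 ± 0.148 FPKM. The second Nnt gene ID was at 2.61, 0.414 and 2.29 FPKM in the libraries labelled CD22 knockout, with a mean of 1.77, and listed at 0 in each wild type library. In the other direction, Car6 was at 0.211 ± 0.062 against 0.888 ± 0.410 FPKM and Aldh1a7 at 0.101 ± 0.074 against 0.467 ± 0.141 FPKM.

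Transcripts of other tissues appeared in single wild type libraries. Wild type library 2 held 37.2 FPKM of epididymis transcripts, a list on which 19 of the 20 genes with any value were highest there, against at most 0.213 FPKM in any other library. Wild type library 1 held 8.90 FPKM of skeletal muscle transcripts against 0.931 to 1.36 in the others, and 53.7 FPKM of adipocyte transcripts, where 5 of the 9 genes are also in the main test, against 8.05 to 25.7. RNA or reads from epididymis may account for the first, since 8 of 9 Defb genes outside that list were also highest in wild type library 2. Skeletal muscle left on the bone may account for the second, and 7 of 13 genes of a second muscle list were highest in wild type library 1. The summed FPKM of that second list was 8.61 there against 8.30 to 10.8 elsewhere. Of its genes highest there, Ttn, Cacna1s, Neb, Trdn and Casq1 were at only 0.011 to 0.051 FPKM in wild type library 1. Ryr1 was at 0.327 there against 0.305 in wild type library 3, and Pygm at 0.574 against 0.130 to 0.267 elsewhere. The second list therefore lends the muscle explanation little weight. No biological explanation was tested, and none of the epididymis genes or the first muscle list's genes was among those tested between the groups.

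Capza1 rose while its pseudogene Capza1-ps1 fell, and the 2 overlapping Nnt IDs also moved apart. Summed FPKM of Capza1 and its pseudogene was 89.4 ± 2.14 in the libraries labelled CD22 knockout and 104 ± 6.31 in wild type, a log2 fold change of -0.21 against 0.98 for Capza1 alone. The summed values still did not overlap between the groups. Reads shared between Capza1 and its pseudogene could therefore account for most of both changes, with a sequence difference between the mice as an untested reason for the reads to move. Summed Nnt was 3.62 ± 0.758 against 5.52 ± 0.886 FPKM, a log2 fold change of -0.50 against -1.20 for the called ID, and did not overlap between the groups. Whether Nnt fell or its reads were split differently cannot be told apart, because gene-level values do not show which exons were read.

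Among the 10 splits of the 6 libraries into 3 and 3, the real split called 44 genes and the highest other split 3, and 1 of the 10, the real one, gave as many. For the gene lists, the real split called 5 and the highest other split 8, and 5 of the 10 gave as many. With 10 splits a share under 0.05 cannot be reached.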

How the results depend on the processing

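The fits without wild type libraries 1 and 2 together, which leave 1 wild type library assumed to vary like the others, and of protein-coding genes alone were chosen after the results were seen. The 44 called genes became 3 with no filter on low values, 10 with at least 2-fold as well, 78 at an adjusted p below 0.1 and 11 without both libraries (7 of them among the 44), and ran from 28 without CD22_KO replicate 2 to 92 without CD22_KO replicate 3. A pseudocount of 0.1 gave 43 (all 43 shared), an FPKM of at least 5 gave 39, median centring 38, quantile normalization 36, no robust moderation 38 and protein-coding genes alone 58. With no filter 25499 genes were tested, and the added low genes change both the trend and the adjustment; a threshold of 0.1 or of 2-fold changes the count by its construction; the cause of the other shifts was not tested. Adding the replicate number as a block gave 63 called genes, 36 of them shared. Deviations of same-numbered libraries of the 2 groups correlated at 0.056, -0.034 and 0.070, so no large shared deviation was seen. Such correlations cannot show whether same-numbered libraries were prepared together. The 44 genes kept their sign with any single library left out, 21 were called in each of those 6 fits, and Cd22 was called in no alternative. The 5 called lists became 3 with no filter, 0 with an estimated correlation, 0 by the directional fry test, 4 with the replicate block, and 1 (without CD22_KO replicate 2) to 7 (without CD22_KO replicate 1 or WT replicate 3) with a library left out. Among fixed neighbours of Cd22, 0 became 1 with an FPKM of at least 5, at an adjusted p below 0.1 and with protein-coding genes alone, and ran from 0 to 1 (without WT replicate 2) with a library left out; within 5 Mb 0 genes and within 20 Mb 3 of 306 were called (odds ratio 2.52, Fisher's exact test, p = 0.129), in place of 2 within 10 Mb. Annotation terms stayed at 0 with the calls made without robust moderation. Signs turned for named genes that were called in no fit. Without both libraries, log2 fold changes were -0.084 for Mmp8, 0.078 for Irf8, 0.20 for Acta2, 0.040 for Hbb-bs, 0.026 for Uty and 0.023 for Kdm5d, and with median centring 0.013 for Acta2 and 0.016 for Kdm5d. With 1 library left out, they ran from -0.021 to 0.26 for Ccr2, -0.12 to 0.26 for Csf3r, -0.032 to 0.045 for Blnk, -0.11 to 0.0041 for Itgax, -0.094 to 0.0011 for Irf8, -0.42 to 0.20 for Sparc, -0.11 to 0.11 for Acta2, -0.073 to 0.32 for Pf4, -0.11 to 0.028 for Uty and -0.067 to 0.074 for Kdm5d; the cause was not tested. The other tests and normalizations set beforehand for read counts (DESeq2, limma-voom and other size factors) were not run because the values are FPKM, and with unknown depth the precision of low genes cannot be given.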

Other observations

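Genes in this part were chosen after their values were seen, as were the test of overlapping genes and the comparison of other splits with random sets, while the other tests of splits and of uncalled neighbours were set before their results were seen. Several called genes outside the naming rule had known roles in macrophages or growth. Fcrls, an Fc receptor-like scavenger receptor gene, rose 1.42-fold in the libraries labelled CD22 knockout, from 264 ± 18.2 to 374 ± 16.1 FPKM (SD, n = 3 each, limma, log2 fold change 0.50). Hmga2, a chromatin protein gene, fell from 2.83 ± 0.270 to 1.32 ± 0.0492 FPKM, Plxna1, a semaphorin receptor gene, from 84.6 ± 4.63 to 61.4 ± 3.66 FPKM, and Parvg, a gene of integrin-linked adhesion, from 13.8 ± 0.425 to 9.27 ± 1.06 FPKM. Rab15, like Rab4a a small GTPase of endosomes, fell from 1.17 ± 0.0837 to 0.391 ± 0.0531 FPKM. The GTPase gene Gem fell from 3.46 ± 0.531 to 1.81 ± 0.106 FPKM. Of these, Hmga2 alone was called with any single library left out; Fcrls and Plxna1 lay close to the threshold (limma, adjusted p = 0.0498 for both), and Parvg, Rab15 and Gem were at adjusted p of 0.0295, 0.0142 and 0.0168.

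On chromosome 16, 6 genes were called in 2 groups of neighbours. Ift57, Cd47 and Dubr lie between 49.7 and 50.7 Mb in GRCm38, and Tbc1d23, Cmss1 and Dcbld2 between 57.2 and 58.5 Mb. Cd47 fell from 44.4 ± 1.70 to 28.7 ± 0.918 FPKM, Ift57 from 4.04 ± 0.263 to 2.07 ± 0.238, Tbc1d23 from 12.8 ± 0.326 to 6.66 ± 0.458, Cmss1 from 2.47 ± 0.0248 to 1.54 ± 0.121 and Dcbld2 from 8.58 ± 0.585 to 4.88 ± 0.358, while Dubr rose from 3.22 ± 0.362 to 5.47 ± 0.428 FPKM (SD, n = 3 each). The calls of Cmss1 (limma, adjusted p = 0.0479) and Dubr were lost in at least 1 fit with a library left out, and those of the other four were kept in each.

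The 44 called genes formed 10 pairs closer than 2 Mb that did not overlap, against a mean of 2.84 in 10000 random sets of tested genes (permutation p = 0.0029), so overlapping genes that share reads do not account for all of them. With a distance of 5 Mb the excess was weaker, at 12 pairs against a mean of 5.52 (permutation p = 0.0222). The counts below are for 2 Mb. Of the 9 other splits of the libraries, 6 gave 1 to 5 close pairs among as many top genes, within the 95th percentile of 6 in random sets. The 3 that kept CD22_KO replicates 1 and 2 together gave 8 to 10, so whether neighbouring genes move together apart from genotype stays open. Inherited segments that differ between the mouse lines are another candidate explanation. In uncalled neighbours of called genes an unadjusted p under 0.05 was more frequent (14% against 10.2%, odds ratio 1.43, 1.17 to 1.73, Fisher's exact test, p = 3.2e-04), and the odds ratio ran from 0.771 to 1.39 in the other splits. Some of those splits also passed 0.05 (Fisher's exact test, p = 0.0241, 0.0387 and 0.0494). The test treats neighbouring genes as independent, so its p can be too small. These explanations cannot be told apart here, because every other split still keeps 2 libraries of each group together, and the Nnt deletion known in C57BL/6J mice makes the substrain of each group a point to check.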
